A study of Homo sapiens with 6 samples.

How the data were processed

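Gene expression was measured on Affymetrix human transcriptome arrays in U937 cells, 3 arrays from cells infected with a negative control lentivirus and 3 from cells infected with a lentivirus carrying a miR-608 inhibitor. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was extracted with Trizol and biotin-labelled cRNA was made from 0.25 µg of it. The deposited values are log2 expression values, 1 per transcript cluster and array, made by RMA per the submitters' processing notes. RMA corrects background, normalizes between arrays and summarises probes. The log base was taken from RMA's convention and fits the range of the values. The software that ran RMA, its version, the annotation release and the genome build are not given in the sources used here, so no coordinates are printed. The array medians were 5.09, 4.96 and 5.01 in the controls and 4.99, 5.00 and 5.04 in the inhibitor arrays. Scanner intensities were not used here, so background correction and RMA itself could not be varied. RMA shrinks differences between dim clusters, so fold changes of genes near the floor are likely to be understated. Precision is limited by the number of arrays.

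Gene names came from the platform annotation, which can be old, matched by cluster ID. Of 67528 transcript clusters 23781 had 1 gene symbol, 1543 had several and 42204 had none here. Only clusters with 1 symbol were named. Each gene was read from its brightest cluster, by the mean over all 6 arrays, which gave 22465 genes, 479 of them with more than 1 cluster. Of the 554 distinct genes on the fixed lists, 480 were measured under their names, and the others were not analysed here. Near-identical genes, among them HLA genes, small nucleolar RNA copies and U6 copies, may share signal and cannot be kept apart with confidence.

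The inhibitor was compared with the control by limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the default prior, group as the only term) on the deposited log2 values. Benjamini-Hochberg adjustment ran over the 22465 genes, and separately over all clusters, with a threshold of 0.05. No filter on dim clusters was applied. An exact permutation test of 3 arrays against 3 cannot give a two-sided p below 0.1, so single genes were tested only in the limma model. The 23 gene lists were tested with camera (preset correlation 0.01, two-sided), adjusted over the lists. Of these, 1 list is counted in the totals but not reported here. The others were reported miR-608 targets, type I interferon response, NF-kB inflammatory genes, monocyte and macrophage differentiation, azurophil granule and phagocyte oxidase, MHC class II, MHC class I presentation, mitosis, DNA replication, p53 targets, apoptosis regulators, unfolded protein and amino acid stress response, heat shock, cholesterol synthesis, hypoxia and glycolysis, oxidative phosphorylation, cytosolic ribosomal proteins, immediate early genes, microRNA pathway, replication-dependent histones, other blood cell markers, and epithelial and fibroblast markers. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance in 1 direction without reference to other genes, were run beside it.

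The groups, the tests, the lists, the naming rule and the alternatives were set before the data were examined. The rule named the 12 largest increases and 12 largest decreases among genes past the threshold whose arrays did not overlap between groups and whose mean in the higher group reached the median gene level of 6.18, leaving out uncharacterised loci. It also named MIR608's host gene, the reported targets, and up to 4 called members of each called list or list with at least 3 called members (up to 2 otherwise). Since no gene passed with all 6 arrays, the rule was applied to the planned fit without control replicate 1, in which 2052 genes met it. That fit was chosen for naming after the results were seen, as the only one of the 6 left-out-array fits that called any gene. The alternatives were quantile normalization, median centring, filters at the 25th percentile and the median of all clusters, a trended robust prior, array weights, the replicate number as a block, the mean of all clusters of a gene, and leaving out each array in turn. The same settings and a further left-out array applied to the 5 remaining arrays, and a gene-by-gene form of the array weights were added after the data were seen. Lists of ribosome biogenesis genes, lysosomal genes and small RNA families were also added then. A planned test of miR-608 seed sites was not run, since no transcript sequences were used here, and a planned filter on cross-hybridising clusters removed nothing, since 0 cluster IDs carry such a suffix.

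The fits were tested on simulated data with known changes for 22465 genes. In the design of 6 arrays 25.4% of genes changed by 0.5 (log2) were recovered, 70% of those changed by 1 and 96.7% of those changed by 2, and in the design of 5 arrays 53.6%, 89.2% and 100%. False calls were 5.80% and 5.29% of all calls, and with no gene changed both designs called 0 genes and 0 lists. The simulated noise was independent between genes, and no simulated array stood apart from the others. In the data the estimated correlation within the interferon list was 0.98 with all 6 arrays. The simulated rates therefore need not hold here, and they do not show how often lists of correlated genes are called. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.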

Results

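Gene expression was measured in U937 cells, an established human pro-monocytic line derived from a histiocytic lymphoma. The cells were infected with a lentivirus that carried an inhibitor of the microRNA miR-608 or with a negative control virus, and 3 arrays were run for each of these groups. RNA was taken at 72 h, and the labels put the share of cells positive for GFP above 90% by 3 days after infection. Each array gave a summarised log2 expression value for 67528 transcript clusters, from which 22465 genes were compared. The number of arrays limits the precision of every value. The labels do not say that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. In what follows, levels are mean log2 values ± SD (n = 3 per group), and log2 fold changes are inhibitor minus control ± the standard error of the limma fit.

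The arrays did not fall into 2 even groups. Control replicate 1 stood apart from the other 5 arrays, with Pearson correlations over all transcript clusters of 0.972 to 0.982 against them. The other 5 arrays correlated with each other at 0.991 to 0.997, and the 3 inhibitor arrays at 0.994 to 0.997. These correlations run across transcript clusters, which are not independent replicates. The first principal component held 58.5% of the variance and set control replicate 1, at 84.9, against control replicates 2 and 3, at -38.9 and -25.6. The inhibitor arrays lay between -11.5 and -2.42 on it. The second component held 20.9% and separated the inhibitor arrays, at -28.5 to -16.2, from the controls, at 14.5 to 28.5. No pair of arrays held identical values.

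**Figure D1:**
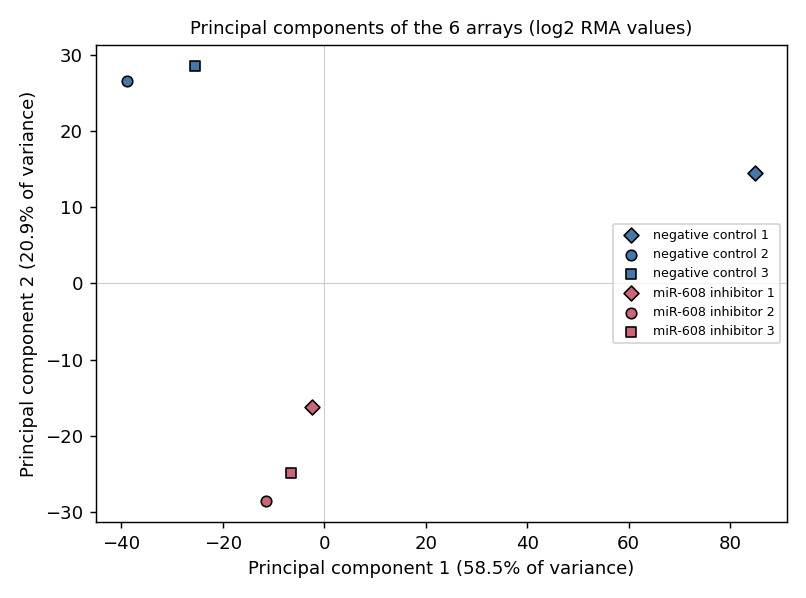
Each point is 1 array, placed on the first principal component (horizontal axis, 58.5% of the variance) and the second (vertical axis, 20.9%) of the log2 values, with negative controls in blue and miR-608 inhibitor arrays in red. Control replicate 1 sits alone at 84.9 on the first component, and the second component places all 3 inhibitor arrays below all 3 controls.

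The cluster over the MIR608 locus was dim in both groups, at 4.18 ± 0.11 in the controls and 4.39 ± 0.22 in the inhibitor arrays, with a log2 fold change of 0.20 ± 0.13 (limma adjusted p = 0.899). Its values were 4.26, 4.23 and 4.06 in the controls and 4.58, 4.15 and 4.43 in the inhibitor arrays. This cluster reads RNA of the precursor locus and does not measure the mature microRNA or its blocking. SEMA4G, the gene whose intron holds MIR608, was at 5.65 ± 0.15 and 5.60 ± 0.04, with a log2 fold change of -0.05 ± 0.10. Of the 12 genes fixed as reported miR-608 targets, 10 were analysed here, and limma called 0 of them with all 6 arrays, over all genes or adjusted over the list alone, with none below an unadjusted p of 0.05. Their log2 fold changes were 0.15 for MIF, 0.10 for TFAP4, 0.09 for CD44, 0.06 for RAC2, 0.03 for AKT2, -0.01 for BCL2L1, -0.02 for EGFR, -0.03 for both ACHE and CDC42, and -0.27 for IL6, with standard errors of 0.08 to 0.25. As a list they were not called by limma's camera test, which sets a list against the other genes (mean log2 fold change 0.0063, adjusted p = 0.875), and without control replicate 1 neither (adjusted p = 0.769). Without control replicate 1, CD44, a cell surface receptor for hyaluronan, rose by 0.40 ± 0.07 (adjusted p = 0.0138), and 2 of the 10 rose when adjusted over the list alone, where RAC2 had a log2 fold change of 0.26 ± 0.07 (adjusted p = 0.0671 over all genes). For both genes control replicate 1 lay above every inhibitor array, at 9.31 against 8.72 to 8.79 for CD44 and at 9.68 against 9.31 to 9.41 for RAC2. Averaging the clusters of CD44 gave a log2 fold change of -0.03 over all 6 arrays.

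The comparison of the inhibitor with the control virus asks which transcripts differ when miR-608 is inhibited. With all 6 arrays, the gene with the lowest p was CD4 (cluster TC12000092.hg.1), a surface receptor that monocytic cells share with helper T cells, at 8.27 ± 0.13 in the controls and 9.38 ± 0.07 in the inhibitor arrays (log2 fold change 1.11 ± 0.09). Close behind were HIBADH, an enzyme of valine breakdown (0.85 ± 0.08), ACAD11, an acyl-CoA dehydrogenase (0.93 ± 0.09), the lysosomal genes GM2A (0.88 ± 0.09) and MANBA (0.64 ± 0.08), and CSF3R, the receptor for granulocyte colony-stimulating factor (0.65 ± 0.07). Lower values stood in the inhibitor arrays for EPB41L3, a membrane skeleton protein (-0.80 ± 0.08), IPCEF1 (-0.71 ± 0.08) and MOB3A (-0.67 ± 0.08). These genes, chosen after their values were seen, belong to 18 that shared the lowest adjusted p, 0.0946, with 15 higher and 3 lower in the inhibitor arrays. limma therefore called 0 of 22465 genes at an adjusted p under 0.05, in either direction and at any fold size, and 0 of 67528 transcript clusters. At an unadjusted p under 0.05 there were 1791 genes, 1129 higher and 662 lower. Weighting the arrays gene by gene gave 3291 genes. That weighting took weight from control replicate 1 and put most control weight on control replicate 3, with weights of 0.13, 0.70 and 4.23 on control replicates 1, 2 and 3. A restricted maximum likelihood weighting, whose iteration stopped early with nearly all control weight on control replicate 3, gave 7151. Averaging all clusters of a gene gave 1 gene, ACSM3, at 5.60 ± 0.08 and 7.27 ± 0.04 (log2 fold change 1.67 ± 0.07, adjusted p = 0.00439). The 3 inhibitor values lay wholly above or below the 3 control values for 3176 genes, 14.1% against the 10% that chance gives on average. Genes move together, so the share in a single split can lie far from that average, and other splits were not counted this way.

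Most of the spread among the controls lay in control replicate 1. Its inflammatory and interferon-induced transcripts were far above those of the other controls. CXCL10, an interferon-induced chemokine, was at 10.54 in control replicate 1 against 4.52 and 4.55 in replicates 2 and 3, RIGI, a sensor of viral RNA, at 9.71 against 5.43 and 5.25, and IL1B, an inflammatory cytokine, at 12.05 against 6.55 and 6.28. Monocyte surface genes followed, with the lipopolysaccharide co-receptor CD14 at 8.82 against 5.32 and 5.33 and the costimulatory ligand CD86 at 7.50 against 3.95 and 3.95. These genes were chosen after their values were seen. On control replicate 1, 520 genes were at least 2-fold above the mean of the other controls and 601 at least 2-fold below, while 0 genes differed 2-fold between control replicates 2 and 3. The median absolute difference was 0.231 for control replicate 1 from that mean and 0.0879 between control replicates 2 and 3.

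Because the fit of all 6 arrays called no gene, genes were named from the fit without control replicate 1. All 6 left-out-array fits were planned before the data were examined, but this one was taken for naming after the results were seen, as the only one that called any gene. In it CD38 (cluster TC04000145.hg.1), an enzyme that consumes NAD on the cell surface, rose most among the named genes, 12.4-fold, with a log2 fold change of 3.63 ± 0.11 (limma adjusted p = 0.000101) and a level of 8.60 ± 0.16 in the inhibitor arrays against 4.90 and 5.03 in control replicates 2 and 3. MS4A4A, a macrophage membrane protein, rose by 2.61 ± 0.09, TNFAIP6, a hyaluronan-binding protein induced by inflammatory cytokines, by 2.49 ± 0.10, and CYBB, the catalytic subunit of the phagocyte NADPH oxidase, by 2.37 ± 0.11. SAT1, the rate-limiting enzyme of polyamine breakdown, rose by 2.06 ± 0.08, GPRIN3 by 2.05 ± 0.10, the interferon-induced IFI6 by 1.93 ± 0.11, and KYNU, kynureninase of tryptophan breakdown, by 1.73 ± 0.08. The remaining increases were the nucleolar RNA SNORD71 (1.89 ± 0.33, adjusted p = 0.0151), TASL, an adaptor of endosomal Toll-like receptor signalling (1.61 ± 0.09), the cytokine receptor IL31RA (1.61 ± 0.08) and the interferon-induced SAMD9L (1.59 ± 0.12).

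Among decreases in the same fit, NCOA5, a nuclear receptor coregulator, fell by 1.47 ± 0.07 and the long noncoding RNA LINC00906 by 1.41 ± 0.13. UTP20 and LTV1, both factors of small ribosomal subunit assembly, fell by 1.40 ± 0.10 and 1.07 ± 0.12, and POLR3B, a subunit of RNA polymerase III, by 1.15 ± 0.10. HSPH1, a cytosolic chaperone, fell by 1.26 ± 0.11, the Polycomb group gene SFMBT2 by 1.17 ± 0.09, and the semaphorin receptor PLXNC1 by 1.09 ± 0.08. CYP1A1, a monooxygenase induced through the aryl hydrocarbon receptor, fell by 1.08 ± 0.08, CEACAM6 by 1.07 ± 0.07, the pseudokinase TRIB2 by 1.06 ± 0.09 and the microRNA locus MIR4521 by 1.06 ± 0.15. Adjusted p-values of these 12 decreases ran from 0.000331 to 0.00728.

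Without control replicate 1, limma called 2351 of the 22465 genes, 1107 higher and 1244 lower, with 91 changed at least 2-fold, and 3971 transcript clusters. The inhibitor arrays lay wholly to one side of the remaining controls for 9208 genes, 41.0% against the 20% that chance gives on average. Here too the share in a single split can lie far from that average, and other splits were not counted this way. Over all 6 arrays the log2 fold changes of all 12 named increases were smaller, with CD38 at 2.49 ± 0.87, MS4A4A at 1.35 ± 0.96, SAT1 at 0.66 ± 1.07, IFI6 at 0.60 ± 1.02, KYNU at 0.35 ± 1.05, TNFAIP6 at 0.28 ± 1.69 and SAMD9L at -0.05 ± 1.26. Decreases were smaller there as well, with LINC00906 at -0.62 ± 0.61, LTV1 at -0.58 ± 0.39, UTP20 at -0.57 ± 0.64 and PLXNC1 at -0.51 ± 0.45, whereas CYP1A1 was at -1.26 ± 0.16. Control replicate 1 exceeded every inhibitor array for 7 of the 12 named increases, such as TNFAIP6 (11.21 against 7.06 ± 0.17) and CYBB (11.93 against 10.35 ± 0.17). It lay below every inhibitor array for 4 of the 12 named decreases, such as UTP20 (5.76 against 6.87 ± 0.13). Among all genes called in this fit, it lay above control replicates 2 and 3 for 853 of 1107 increases. It lay below them for 1151 of 1244 decreases. Both the calls and these positions are taken against the same 2 controls. For TASL control replicate 1, at 8.58, lay between the other controls (7.92 and 7.70) and the inhibitor arrays (9.37 to 9.48). It also lay between them for SFMBT2, at 8.30 (8.85 and 8.73, 7.48 to 7.71), and TRIB2, at 7.31 (7.91 and 7.66, 6.71 to 6.74). For CYP1A1, at 7.54, it lay beyond the other controls (7.04 and 6.95), away from the inhibitor arrays (5.83 to 6.01). For GPRIN3 and POLR3B, at 8.49 and 6.07, it lay within the range of the inhibitor arrays. The count varied with the remaining arrays: it was 303 when control replicate 2 was also left out, 455 without control replicate 3, and 2566, 1161 and 1286 without inhibitor replicate 1, 2 or 3.

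**Figure D2:**
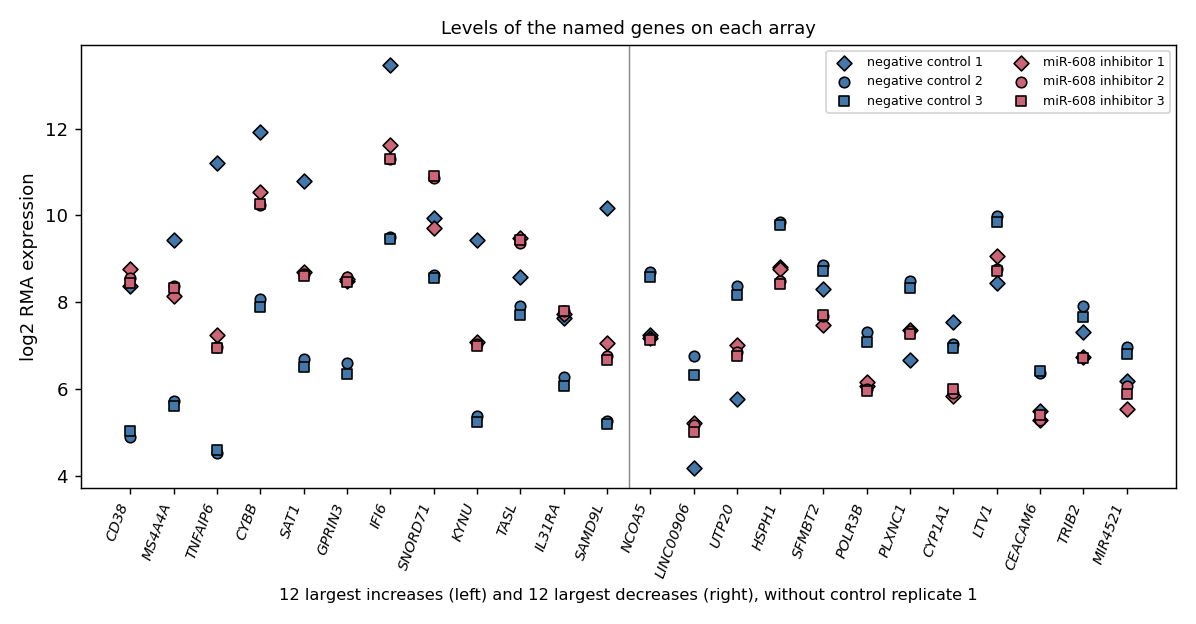
Each point is the log2 expression (vertical axis) of a gene (horizontal axis) on 1 array, for the 12 largest increases and the 12 largest decreases in the fit without control replicate 1. Negative controls are in blue and inhibitor arrays in red. For CD38, control replicate 1 is at 8.38, close to the inhibitor arrays at 8.60 ± 0.16 and far from the other controls at 4.90 and 5.03.

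Gene lists fixed before the data were examined were tested with camera. With all 6 arrays 12 of the 23 lists were called, 5 higher and 7 lower, and without control replicate 1 there were 14, 8 higher and 6 lower. With an estimated correlation between genes camera called 0 lists in either fit, with 2 and 6 lists at an unadjusted p under 0.05, and the fry test called 2 and 12. Of the lists called in both fits, 6 kept their direction and 3 turned. Counts of members that rose or fell below come from the fit without control replicate 1, since limma called no single gene over all 6 arrays.

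As a list, genes of the azurophil granule and phagocyte oxidase were higher in the inhibitor arrays in both fits. Of 18 measured members 8 rose and none fell (10 rose and 1 fell adjusted over the list alone), among them CYBB, the granule protease homologue AZU1 (0.74 ± 0.10), the oxidase subunit NCF1 (0.74 ± 0.07) and the protease PRTN3 (0.73 ± 0.07). The mean level of the list was 10.02 ± 0.02 in the inhibitor arrays, above 9.77, 9.63 and 9.63 in the controls. Camera gave an adjusted p of 0.000649 with all 6 arrays (mean log2 fold change 0.35, 4 members higher adjusted over the list alone, adjusted p = 0.321 with an estimated correlation). The fit without control replicate 1 gave 1.57e-06 (mean 0.39, adjusted p = 0.164 with an estimated correlation). AZU1 and PRTN3 were lower on control replicate 1 than on the other controls, at 8.35 and 8.18, and with all 6 arrays their log2 fold changes were 0.97 ± 0.20 and 1.07 ± 0.27. CYBB and NCF1 were higher on control replicate 1 than on any inhibitor array, and over all 6 arrays CYBB was at 1.05 ± 1.01 and NCF1 at -0.16 ± 0.69, with NCF1 at 11.01 on control replicate 1 and 9.04 ± 0.03 on the inhibitor arrays. NCF1 has near-identical pseudogene copies, so its signal may include theirs.

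Of 28 monocyte and macrophage differentiation genes 11 rose over all genes without control replicate 1 and 1 fell (12 and 1 adjusted over the list alone). The integrin subunits ITGAM and ITGAX rose by 1.495 ± 0.073 and 1.11 ± 0.08, the macrophage lysosomal glycoprotein CD68 by 1.48 ± 0.06, and the myeloid receptor TREM1 by 1.40 ± 0.07. The calcium-binding S100A8, named after its value was seen, fell by 0.40 ± 0.08. The list's mean log2 fold change was 0.35 (camera adjusted p = 2.15e-06, adjusted p = 0.174 with an estimated correlation). With all 6 arrays the mean was -0.12 (adjusted p = 0.484), with the list at 8.07 on control replicate 1, 6.65 and 6.66 on the other controls and 6.999 ± 0.026 on the inhibitor arrays.

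Interferon response and inflammatory genes gave opposite directions in the fits. Without control replicate 1, 13 of 33 type I interferon response genes rose and none fell (17 and 1 adjusted over the list alone), with IFI6, SAMD9L, the RNA sensor IFIH1 (1.10 ± 0.10) and the oligoadenylate synthetase OAS2 (1.13 ± 0.07) changing most. Of 24 NF-kB inflammatory genes 11 rose and 2 fell (12 and 2 adjusted over the list alone): IL1B rose by 1.55 ± 0.11, the feedback inhibitor TNFAIP3 by 1.36 ± 0.07 and the adhesion molecule ICAM1 by 0.78 ± 0.08, while the cytokine TNF fell by 0.82 ± 0.09 and the chemokine CCL2, named after its value was seen, by 0.50 ± 0.07. The mean log2 fold changes were 0.40 for interferon genes (camera adjusted p = 9.41e-11, adjusted p = 0.0988 with an estimated correlation) and 0.31 for NF-kB genes (2.25e-05, adjusted p = 0.140 with an estimated correlation). With all 6 arrays these means were -0.49 and -0.52, each with a camera adjusted p of 0.0134 and an adjusted p of 0.860 with an estimated correlation. The interferon list stood at 8.53 on control replicate 1, 5.87 and 5.85 on the other controls and 6.26 ± 0.02 on the inhibitor arrays, and the NF-kB list at 8.74, 6.24, 6.25 and 6.55 ± 0.02.

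Immediate early genes, transcription factors and regulators induced within minutes of a stimulus, turned in the same way. Of 28 genes 5 rose without control replicate 1 and none fell (8 and 2 adjusted over the list alone): IER3 (0.81 ± 0.14), DUSP6 (0.69 ± 0.09), NR4A2 (0.39 ± 0.07), FOS (0.38 ± 0.07) and JUN (0.34 ± 0.07), the last named after its value was seen. The mean was 0.12 (camera adjusted p = 0.0323, adjusted p = 0.230 with an estimated correlation). It was -0.19 with all 6 arrays (adjusted p = 0.0134, adjusted p = 0.860 with an estimated correlation), with the list at 7.89 on control replicate 1 and 7.07 ± 0.01 on the inhibitor arrays.

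In antigen presentation, 5 of 12 MHC class II genes rose and none fell when control replicate 1 was left out, the same count adjusted over the list alone: the peptide-loading gene HLA-DMA (1.14 ± 0.11), the invariant chain CD74 (0.67 ± 0.08), HLA-DRA (0.55 ± 0.07), HLA-DRB1 (0.55 ± 0.08) and the transactivator CIITA (0.41 ± 0.08), the last named after its value was seen. The class II mean was 0.30 (camera adjusted p = 0.000524, adjusted p = 0.164 with an estimated correlation), and with all 6 arrays 0.17 (adjusted p = 0.0327, 3 members higher adjusted over the list alone, adjusted p = 0.860 with an estimated correlation). The class II call with all 6 arrays was lost without clusters under the median and with the replicate number as a block. It was also lost without control replicate 2, control replicate 3 or inhibitor replicate 1. Of 15 MHC class I presentation genes 9 rose and none fell (10 adjusted over the list alone), including HLA-B (0.88 ± 0.07), HLA-E (0.82 ± 0.08), HLA-C (0.73 ± 0.07) and HLA-G (0.66 ± 0.07). The class I mean was 0.38 (adjusted p = 1.61e-07, adjusted p = 0.230 with an estimated correlation) and 0.12 with all 6 arrays (adjusted p = 0.125). Control replicate 1 lay above every inhibitor array for the mean of both lists, at 5.99 against 5.87 to 5.94 for class II and at 8.80 against 8.33 to 8.42 for class I. Single class II genes differed. Every inhibitor array lay above all 3 controls for 4 of them, HLA-DMA, CD74, HLA-DRA and CIITA, and for 0 class I genes. HLA-DRB1 was at 9.39 on control replicate 1, above every inhibitor array. HLA genes are near-identical and several clusters lie on alternative haplotypes, so single HLA genes cannot be kept apart with confidence.

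In cell division, 18 of 26 mitosis genes fell and none rose when control replicate 1 was left out (19 adjusted over the list alone), with the kinesins CENPE (-0.81 ± 0.11) and KIF11 (-0.77 ± 0.11), cyclin CCNB1 (-0.72 ± 0.08) and the kinase PLK1 (-0.71 ± 0.08) changing most. The mitosis mean was -0.46 without control replicate 1 (camera adjusted p = 1.31e-15, adjusted p = 0.140 with an estimated correlation) and -0.30 with all 6 arrays (adjusted p = 8.94e-09, adjusted p = 0.693 with an estimated correlation). Control replicate 1 was at 8.59 for this list, level with the inhibitor arrays at 8.60 ± 0.06 and below the other controls at 9.10 and 9.01. In the same fit 9 of 24 DNA replication genes fell and none rose (11 adjusted over the list alone), including the cyclin CCNE2 (-0.76 ± 0.11), the polymerase subunit POLA1 (-0.66 ± 0.09), the licensing factor CDC6 (-0.58 ± 0.07) and the flap endonuclease FEN1 (-0.54 ± 0.09). That list had a mean of -0.26 (adjusted p = 1.61e-07, adjusted p = 0.230 with an estimated correlation) and of 0.02 with all 6 arrays (adjusted p = 0.690), with control replicate 1 at 8.05, the other controls at 8.93 and 8.86 and the inhibitor arrays at 8.64 ± 0.04. CCNE2 was at 7.36 ± 0.09 in all 3 controls and 6.63 ± 0.16 in the inhibitor arrays, a log2 fold change of -0.73 ± 0.11 with an adjusted p of 0.108.

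As a list, heat shock genes were lower in both fits. Of 16 members 5 fell and none rose (12 fell and 1 rose adjusted over the list alone): HSPH1, the co-chaperone DNAJA1 (-0.87 ± 0.10), HSPA4 (-0.61 ± 0.09), HSP90AA1 (-0.60 ± 0.10) and CHORDC1 (-0.47 ± 0.11), the last named after its value was seen. The list stood at 8.65 ± 0.03 in the inhibitor arrays, below 8.80, 9.03 and 8.98 in the controls. Its members were mixed on control replicate 1, which lay below both other controls for 12 of 16 and above both for 4. Those 4 included HSPA1A (10.83 against 8.83 ± 0.10 in the inhibitor arrays) and HSPA6 (8.74 against 7.44 ± 0.07). Every inhibitor array lay below all 3 controls for 5 members. CHORDC1 was at 6.87 on control replicate 1, below every inhibitor array (7.12 to 7.46). Its mean log2 fold change was -0.36 without control replicate 1 (camera adjusted p = 1.61e-07, adjusted p = 0.140 with an estimated correlation) and -0.29 with all 6 arrays (adjusted p = 0.000772, adjusted p = 0.692 with an estimated correlation). Of 28 genes of the unfolded protein and amino acid stress response, the serine synthesis enzyme PSAT1 (-0.43 ± 0.07), DNAJC3 (-0.41 ± 0.10) and the chaperone CALR (-0.31 ± 0.08) fell and EDEM1 (0.47 ± 0.08) rose, against 6 and 2 adjusted over the list alone. The mean was -0.08 (adjusted p = 0.0319, adjusted p = 0.230 with an estimated correlation) and -0.13 with all 6 arrays (adjusted p = 0.0190, adjusted p = 0.452 with an estimated correlation).

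Some genes of the survival and damage lists were called without control replicate 1, a fit in which limma called 2351 of all 22465 genes. The share of called apoptosis regulators was close to that over all genes. Of 28 apoptosis regulators BCL2 (-0.48 ± 0.07), BCL2A1 (-0.39 ± 0.09) and cytochrome c, CYCS (-0.30 ± 0.08), fell and none rose, the same counts adjusted over the list alone. The mean was -0.12 with all 6 arrays (camera adjusted p = 0.0244, adjusted p = 0.693 with an estimated correlation) and -0.07 without control replicate 1 (adjusted p = 0.0526). With all 6 arrays the log2 fold changes were 0.02 ± 0.39 for BCL2, -0.59 ± 0.17 for BCL2A1 and -0.12 ± 0.16 for CYCS. Of 19 p53 target genes AEN (-0.62 ± 0.09), RRM2B (-0.59 ± 0.10) and MDM2 (-0.40 ± 0.09) fell and DDB2 (0.51 ± 0.11) rose, against 4 and 1 adjusted over the list alone, and the list was not called by camera in either fit (adjusted p = 0.0965 and 0.509). With all 6 arrays AEN was at -0.28 ± 0.27, RRM2B at -0.65 ± 0.11, MDM2 at -0.46 ± 0.10 and DDB2 at 0.48 ± 0.11. AEN was at 6.54 on control replicate 1, below every inhibitor array (6.81 to 7.03).

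Cholesterol synthesis and oxidative phosphorylation genes were called higher by camera with all 6 arrays only, and cytosolic ribosomal protein genes in both fits. Cholesterol synthesis genes had a mean of 0.12 with all 6 arrays (camera adjusted p = 0.0327, adjusted p = 0.860 with an estimated correlation) and -0.08 without control replicate 1 (adjusted p = 0.0526), where CYP51A1 (-0.47 ± 0.09), HMGCS1 (-0.37 ± 0.08) and ACAT2 (-0.34 ± 0.08) fell and STARD4 (0.43 ± 0.07) rose of 20, the same counts adjusted over the list alone. Oxidative phosphorylation genes had a mean of 0.15 with all 6 arrays (adjusted p = 8.4e-05, adjusted p = 0.860 with an estimated correlation) and 0.013 without control replicate 1 (adjusted p = 0.995). Cytosolic ribosomal protein genes had means of 0.24 (adjusted p = 4.21e-09, adjusted p = 0.693 with an estimated correlation) and 0.09 (adjusted p = 0.0223, adjusted p = 0.771 with an estimated correlation). The fry test called this list in neither fit (adjusted p = 0.518 and 0.249). Without control replicate 1, the camera call was lost when inhibitor replicate 2 or 3 was also left out. Inhibitor replicate 1, at 9.686, lay just below control replicate 2, at 9.688. Control replicate 1 lay below every other array for these 3 lists, at 6.95, 8.26 and 9.25, against lowest inhibitor values of 7.42, 8.64 and 9.69. Of the 25 and 24 members of these last lists limma called 0 in either fit, over all genes or adjusted over the list alone, and without control replicate 1 the unadjusted p was under 0.05 for 2 and 6 members. Of 28 hypoxia and glycolysis genes NDRG1 (1.01 ± 0.08), P4HA1 (0.67 ± 0.08), ADM (0.34 ± 0.08) and SLC2A3 (0.30 ± 0.07) rose and the glycolytic enzymes HK2 (-0.43 ± 0.07) and TPI1 (-0.35 ± 0.07) fell, against 5 and 3 adjusted over the list alone; ADM and SLC2A3 were named after their values were seen. With all 6 arrays NDRG1 was at 0.59 ± 0.33, P4HA1 at 0.40 ± 0.22, ADM at -0.11 ± 0.35 and SLC2A3 at -0.29 ± 0.45. For each of these genes control replicate 1 lay above every inhibitor array, as for ADM (7.22 against 6.16 to 6.26) and SLC2A3 (9.71 against 8.18 to 8.28). HK2 was at -0.39 ± 0.08 and TPI1 at -0.24 ± 0.12 with all 6 arrays. The hypoxia and glycolysis list was not called by camera (adjusted p = 0.767 with all 6 arrays and 0.802 without control replicate 1).

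Of 14 microRNA pathway genes TNRC6A, a scaffold of the silencing complex (-0.46 ± 0.09), DDX20 (-0.45 ± 0.08) and TSN (-0.35 ± 0.07) fell and none rose (4 fell adjusted over the list alone), with a mean of -0.17 without control replicate 1 (camera adjusted p = 0.00174, adjusted p = 0.230 with an estimated correlation), against -0.00081 with all 6 arrays (adjusted p = 0.671). The list stood at 7.22 on control replicate 1, below every inhibitor array (7.53 to 7.56), and at 7.75 and 7.68 on the other controls.

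Lists of other kinds of cell held no called member. Camera gave adjusted p-values of 0.184 and 0.971 for 16 markers of other blood cells, 0.167 and 0.992 for 13 epithelial and fibroblast markers and 0.751 and 0.734 for 9 replication-dependent histone genes, with all 6 arrays and without control replicate 1. limma called 0 members of these lists over all genes or adjusted over the list alone, and the unadjusted p was under 0.05 for 0 blood cell markers, 0 epithelial and fibroblast markers and 2 histone genes without control replicate 1. The blood cell markers stood at 5.28 on control replicate 1, 5.07 and 5.13 on the other controls and 5.11 ± 0.04 on the inhibitor arrays. Median, mean and test did not share a sign for a few lists that were not called. Without control replicate 1 these were the reported targets (median -0.0074, mean 0.05, test upward), hypoxia and glycolysis (-0.0081, 0.05, upward), oxidative phosphorylation (0.0068, 0.013, downward) and epithelial and fibroblast markers (0.0012, 0.0047, downward), and with all 6 arrays the histone genes (-0.0065, 0.011, upward).

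**Figure D3:**
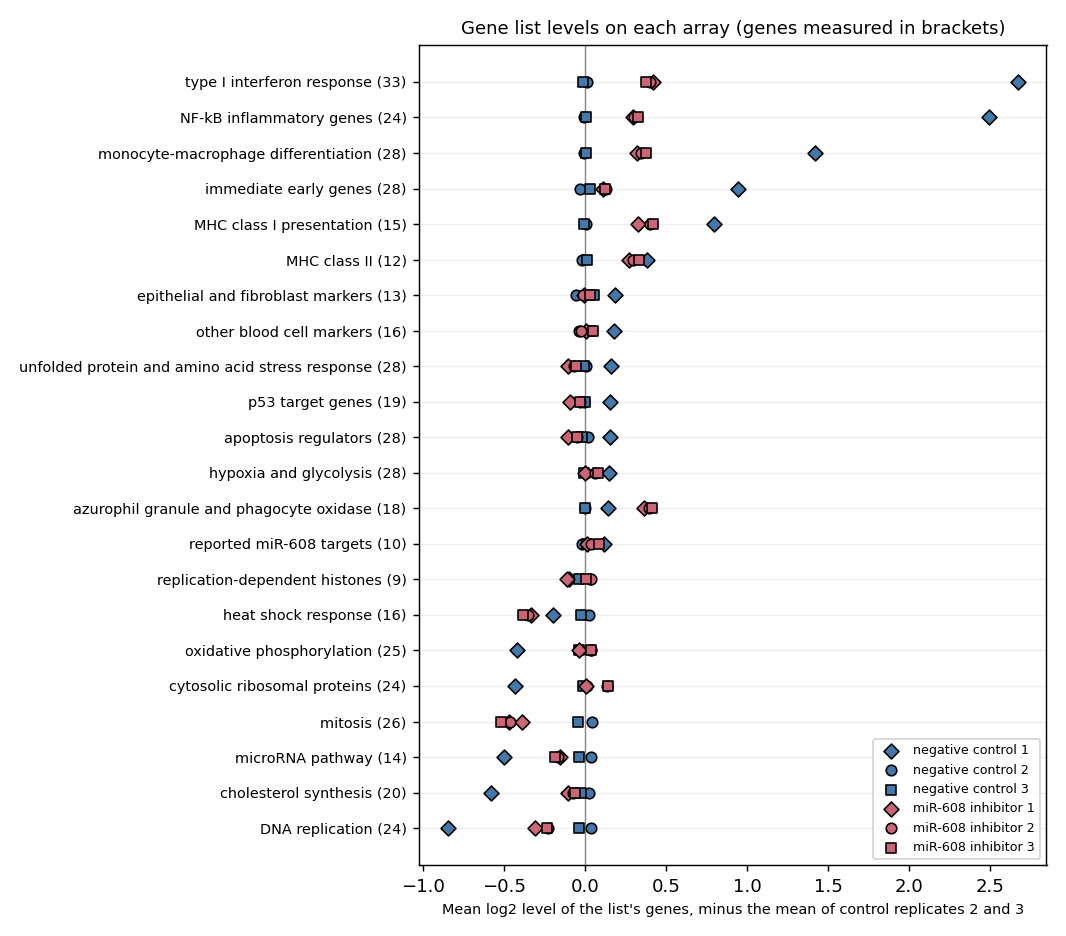
Each point is the mean log2 level of a list's measured genes (vertical axis, number of genes in brackets) on 1 array, minus the mean of control replicates 2 and 3 (horizontal axis, log2), with negative controls in blue and inhibitor arrays in red. Control replicate 1 lies 2.67 above zero for interferon response genes and 2.49 for NF-kB genes, where the inhibitor arrays average 0.40 and 0.31.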

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

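Every further setting applied to the 5 arrays without control replicate 1, and the gene-by-gene array weights, were chosen after the results were seen; all other settings were planned. With all 6 arrays limma called 0 genes (1791 at an unadjusted p under 0.05) as deposited, after quantile normalization or median centring, with either filter on dim clusters and with a trended robust prior, with lowest adjusted p-values of 0.0594 to 0.176. Array weights called 7151 genes (3542 higher, 3609 lower, 122 by 2-fold) and 21344 clusters by the restricted maximum likelihood method, whose iteration stopped early with a weight of 908 on control replicate 3, and 3291 genes (1798 higher, 1493 lower, 93 by 2-fold) and 7616 clusters gene by gene. The mean of all clusters called 1 gene, higher by over 2-fold. Leaving out 1 array gave 0 to 2351 genes, 0 to 1107 higher, 0 to 1244 lower, 0 to 91 by 2-fold and 0 to 3971 clusters, the upper values without control replicate 1; leaving out inhibitor replicate 1 gave 3 clusters and the other arrays none. With the replicate number as a block 0 genes were called (lowest adjusted p = 0.275) and 11 lists; same-numbered arrays deviated together with correlations of 0.114, 0.169 and 0.0646, so the numbers were not taken to pair the arrays, though 5 of 6 arrays correlated best with their own number. Camera called 12 lists with all 6 arrays, 10 without dim clusters and 9 to 14 with 1 array left out, 0 with an estimated correlation and 2 by fry. Without control replicate 1 it called 14, 0 with an estimated correlation (6 at an unadjusted p under 0.05) and 12 by fry. Direction turned without control replicate 1, and the ranges over single left-out arrays were -0.94 to 0.40 for the interferon list, -0.94 to 0.31 for NF-kB genes, -0.36 to 0.35 for monocyte and macrophage genes, -0.37 to 0.12 for immediate early genes, -0.26 to 0.18 for DNA replication and -0.078 to 0.23 for cholesterol synthesis; oxidative phosphorylation ranged from 0.013 to 0.24, where the test's direction turned. SAMD9L ranged from -0.89 to 1.59 and was 1.58 with the array weights whose iteration stopped early and 1.44 gene by gene, not past the threshold (adjusted p = 0.0533); TNFAIP6 ranged from -0.85 to 2.49, KYNU from -0.37 to 1.73, SAT1 from -0.093 to 2.06 and IFI6 from -0.081 to 1.93, with the lowest values, none past the threshold, where control replicate 2 or 3 was left out. Leaving out control replicate 1 removes its level from the control mean, and leaving out control replicate 2 or 3 gives it a larger share of that mean. The ends of these ranges follow from these changes of the control mean. The cause of any other shift was not tested. The 2351 genes called without control replicate 1 became 2137 to 3459 under the same normalizations, filters, prior and cluster mean, and 303, 455, 2566, 1161 and 1286 when control replicate 2, control replicate 3, or inhibitor replicate 1, 2 or 3 was also left out. With 1 control array left, that array is assumed to vary like the inhibitor arrays. The seed site test was not run. For dim clusters, signal over background limits what the arrays can show.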

Other observations

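The lists in this part (ribosome biogenesis, lysosome, small RNA families), the label swap test and the test of signal compression were chosen after the results were seen. The lists were chosen after seeing which genes moved, so their counts describe that observation and no list test is given for them. Ribosome biogenesis genes, which encode the nucleolar factors that process and assemble ribosomal subunits, were lower on the inhibitor arrays than on control replicates 2 and 3: when control replicate 1 was left out, 37 of 47 fell and none rose (42 fell adjusted over the list alone), with UTP20 at -1.40 ± 0.10 and nucleolin, NCL, at -0.44 ± 0.09. The list's mean log2 fold change was -0.51 in that fit and -0.05 with all 6 arrays, with the list at 7.28 on control replicate 1, 8.69 and 8.60 on the other controls and 8.14 ± 0.01 on the inhibitor arrays. Of 34 lysosomal genes 15 rose and 3 fell in the same fit (20 and 4 adjusted over the list alone), with a mean of 0.27. Those that rose, named after their values were seen, included the ganglioside activator GM2A (0.96 ± 0.07), the glycosidases HEXA (0.65 ± 0.10), MANBA (0.64 ± 0.07) and GAA (0.54 ± 0.07) and the ceramidase ASAH1 (0.60 ± 0.09), while FUCA1 (-0.42 ± 0.08), MCOLN1 (-0.34 ± 0.07) and LAMP1 (-0.32 ± 0.08) fell. The lysosomal list stood at 8.78 on control replicate 1, above every inhibitor array (8.62 to 8.69), and at 8.41 and 8.37 on the other controls, so that its mean with all 6 arrays was 0.14.

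Copies of SNORD116, an imprinted cluster of C/D box RNAs, were higher on every inhibitor array than on any control, at 5.48 ± 0.05 against 4.94, 4.98 and 4.85. Their mean log2 fold change was 0.56 with all 6 arrays and 0.57 without control replicate 1. The family was listed after SNORD116-8, SNORD116-14 and SNORD116-15 had been seen among the 18 genes with the lowest adjusted p, so its counts are no independent test. limma called 0 of the 19 copies over all genes with all 6 arrays (15 at an unadjusted p under 0.05, 14 adjusted over the list alone) and 12 without control replicate 1. In the latter fit 39 of 173 C/D box RNAs rose (1 fell), a family that includes the 19 SNORD116 copies and their 12 increases. In that fit 8 of 21 small Cajal body RNAs and 8 of 56 Y RNAs rose too. The mean of each of these families was above every control on each inhibitor array. The margin of the lowest inhibitor array over the highest control was small. It was 4.75 against 4.72 for Y RNAs, 7.11 against 7.08 for small Cajal body RNAs and 5.46 against 5.38 for C/D box RNAs. Only 6 of 56 Y RNA, 14 of 21 small Cajal body RNA and 64 of 173 C/D box clusters were above the median brightness. The other families did not separate this way. There, 50 of 79 U6 RNAs and copies, 23 of 64 H/ACA box RNAs and 28 of 136 other spliceosomal RNAs (2 fell) rose, but U6 RNAs stood at 7.49 on control replicate 1, above every inhibitor array (7.18 to 7.28). H/ACA box and other spliceosomal RNAs stood at 7.72 and 5.12 on control replicate 1, within the range of the inhibitor arrays. Vault RNAs, of which limma called 0 of 5 (1 at an unadjusted p under 0.05), were lower on the inhibitor arrays, at 4.53 ± 0.05. The copies are near-identical, so these counts are not of independent genes.

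Control replicate 1 differed from every other array, among the fixed lists most of all in interferon and NF-kB genes. An exchange of its label with an inhibitor array is argued against, since the lowest correlation within the inhibitor group, 0.994, lay above the highest between an inhibitor array and control replicate 2 or 3, 0.993. A trend on brightness, as signal compression would give, does not account for the deviation of these 2 lists. After a smooth trend on brightness was removed from each array, the interferon list kept 99.2% of its deviation and the NF-kB list 101%. These lists deviated most, and other genes were not tested this way, so compression elsewhere on the array is not addressed. RNA from lymphoid, erythroid or platelet cells would have raised their markers, whose median deviation was 0.171 (upper bootstrap bound 0.265, 0 of 16 markers higher by 1 or more). The rise was small but general, with control replicate 1 above both other controls for 15 of 16 markers. The same held for 12 of 13 epithelial and fibroblast markers (median deviation 0.187), so it was not particular to blood cell markers. A sample from outside the series or a culture in an activated state may each still account for the difference of control replicate 1. The labels give no batch or date, and no biological explanation was tested.

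The changes seen without control replicate 1 ran along the deviation of control replicate 1 itself: over 22465 genes the inhibitor fold change correlated at 0.568 with that deviation, where both are taken against control replicates 2 and 3. Sharing those controls gave 0.447 in simulated unchanged groups, with a covariance of 0.00493 against 0.0647 observed. With no array in common the correlations were 0.428 and 0.574 (covariances 0.0516 and 0.0685), so the shared controls are not the whole cause, and with the brightness trend removed they were 0.455 and 0.557, which argues against that trend. These correlations run across genes, which are not independent replicates. Both of the following readings stay open: the inhibitor arrays may lie part of the way toward the state of control replicate 1, or control replicates 2 and 3 may share a condition that the other 4 arrays lack.

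The higher values of several small RNA families could come from a higher yield of all short RNAs in the inhibitor samples: 6 of 7 classes had a median above 0 in both fits, and the exception, vault RNAs, had no cluster above the median brightness, so this cannot be told apart from a change in their transcription. Host gene transcription was not decided either, since only 2 of 18 listed host genes were measured (median log2 fold change 0.0039), under the share needed for a test.

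Splits of the samples are too few to give a share under 0.05. With all 6 arrays the real split gave 0 genes and the highest of the other 9 gave 0, so all 10 splits were as large, while at an unadjusted p under 0.05 the real split gave 1791 and the highest other 1953. For lists 6 of the 10 splits were as large, with 12 in the real split and 16 in the highest other, the split that grouped control replicate 1 with inhibitor replicates 1 and 3. Of the 5 arrays without control replicate 1 the real split gave 2351 genes and the highest other 0, so 1 of 10 splits was as large. For lists the real split of these 5 arrays gave 14 and the highest other, which grouped inhibitor replicates 1 and 3, also 14, so 2 of 10 splits were as large.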
